A study of Homo sapiens with 18 samples.

How the data were processed

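The series holds 18 arrays of total RNA from 3 acute myeloid leukaemia lines (HL-60, SKM1 and MOLM13). Each line had a hairpin against BCAT1 (shBCAT1) or a non-targeting hairpin (shNT), and each group 3 arrays. Per the labels' protocols, HL-60 was grown with 10% serum and the other lines with 20%, transduced cells were sorted after 48 h, and 200 ng of total RNA was amplified and labelled with biotin for a 1-colour Illumina BeadChip. The labels number the replicates 1 to 3 and do not say whether these were separate cultures, so the p-values measure a spread that may be partly technical. One hairpin against BCAT1 was used, so each comparison is of that hairpin with the control hairpin.

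The deposited value table holds probe intensities on a linear scale, normalized between arrays by the authors. The method and the scanner software are not named in the labels or the table. Background did not seem to have been subtracted, though this is not stated: the smallest value was 60.4, the median 92.1 and the largest 22917.5. The array medians lay between 91.0 and 93.1, a range of 0.0337 on the log2 scale. This is within the limit of 0.1 set beforehand, so the values were not normalized again. No slide or batch was given, and no detection call was used. Of 48107 probes, 15 values in 7 probes were missing.

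Probes were named through a table of the platform's annotation. Of the probes, 30113 had 1 gene symbol, 8 had several and 17986 were not listed there and are unnamed here. The Entrez number of 30074 listed probes was found in the RefSeq gene table, which changed none of the symbols. Each of 20046 genes was represented by its brightest probe over all arrays, and 6691 genes had several probes. Values were taken to log2. A gene was tested when the mean of its brightest group exceeded the median of all probe values, which kept 15288 genes and left out 4758 as dim. For BCL11A, FGR, LFNG, SCAMP1, ITGAX, SLC6A10P and LINC03040, another probe near the median of the table did not follow the bright one.

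Differences were tested with limma 3.58.1 in R 4.3.3, in a single fit with a mean for each of the 6 groups, moderated variances (12 residual and 10.9 prior degrees of freedom) and Benjamini-Hochberg adjustment over the tested genes at 0.05. The contrasts were shBCAT1 minus shNT in each line, the mean of these 3 differences, and an F test of whether they differ, followed by pairwise differences. If background remains in the values, fold changes of dim genes are understated. Calls shared between lines were set against the number that independent lists would share. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

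A set of 32 gene lists was written before the data were examined, as were the tests, the rule for the genes named and all alternatives but the normexp correction. The lists were HIF1 targets, branched-chain amino acid catabolism, glutamate, glutamine and alpha-ketoglutarate metabolism, alpha-ketoglutarate-dependent dioxygenases, amino acid response (ATF4 targets), endoplasmic reticulum unfolded protein response, cholesterol synthesis and uptake, fatty acid synthesis, glycolysis, tricarboxylic acid cycle, oxidative phosphorylation, MYC targets, cytosolic ribosomal proteins, DNA replication and G1/S, mitosis and G2/M, and p53 targets. The others were apoptosis regulators of the BCL2 family, type I interferon response, NF-kB and inflammatory response, immediate early genes, NRF2 and oxidative stress, heat shock and proteasome, autophagy and lysosome, neutrophil granule proteins, myeloid differentiation, stem and progenitor programme, DNA methylation machinery, histone genes, microRNA and shRNA processing, and 3 lists of other cell types (erythroid and megakaryocytic, lymphoid, and epithelial and packaging cells). Some genes stand in several lists: 14 of 19 tested glycolysis genes and 21 of 36 HIF1 targets are also in another list.

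Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 32 lists of a contrast, again with the correlation estimated from the residuals, and with fry. Camera called 61 lists over the 4 contrasts, of which 44 were lost with an estimated correlation. Counts of changed members use the adjustment over all tested genes, with the count adjusted over the list alone beside it.

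The text names BCAT1, then for each contrast up to 10 genes with the largest rise and 10 with the largest fall among genes past the test whose shBCAT1 arrays all lay on the same side of all shNT arrays (in the mean, with the same sign in all lines). It also names the 10 genes with the smallest adjusted p of the F test. For each list and contrast, the 2 to 4 members with the smallest p were eligible for naming. The text names only some of these members, and none for some lists that were not called in a line.

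The procedure was tested on simulated data made from the real means and spread of 15285 genes, with 200 genes changed per contrast. At a log2 change of 1 it recovered 100% of 69 changed genes in HL-60, 98.4% of 61 in SKM1 and 100% of 59 in MOLM13. At 0.5 it recovered 71.6% of 74, 82.9% of 76 and 82.0% of 61, and at 0.25 it recovered 12.3% of 57, 12.7% of 63 and 8.75% of 80. False calls made up 5.84%, 3.55% and 4.13% of the calls. A list shifted by -0.3 in the simulated SKM1 was found, and none of the 32 lists was called in the other lines. The simulated noise was independent between genes, so this does not test the list calls on genes that vary together. By these recovery rates, changes under about 0.5 on the log2 scale are often missed with 3 arrays per group. The real fits called 1704 to 3208 genes per line, which loosens the adjusted threshold, so there the share missed may be smaller.

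Whether arrays with the same replicate number vary together was checked by correlating their deviations from the group means over genes. In MOLM13 the correlations were 0.277, 0.131 and 0.382, all above the 0.1 set as the limit, so in that line the numbers pair the shBCAT1 and shNT arrays; this rests on the values, since the labels give no pairing. The alternatives were no filter and a filter at the 70th percentile, quantile normalization and median centring, an offset of 16, the mean of a gene's probes, array weights, an intensity trend with robust variances, a fit of the arrays of 1 line, a minimum of 1.5-fold, an estimated correlation for the lists, the replicate number as a block, each array left out in turn, and a normexp background correction with an offset of 50, chosen after the data were seen. A planned test of the cell cycle difference between MOLM13 and HL-60 by rescaling the arrays moved nearly nothing (median -0.83 on the log2 scale), so genes matched in intensity, 20 per member, were compared instead. The 17994 probes without a single gene name stayed out of the gene tests.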

Results

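Gene expression was measured on 1-colour Illumina BeadChip arrays in 3 established human acute myeloid leukaemia cell lines, HL-60, SKM1 and MOLM13. Cells of each line had received a lentivirus carrying either a short hairpin RNA against BCAT1 (shBCAT1) or a non-targeting hairpin (shNT), and the transduced cells were isolated by cell sorting 48 h later. BCAT1 is the cytosolic branched-chain amino acid transaminase, which moves the amino group of leucine, isoleucine and valine onto alpha-ketoglutarate and so makes glutamate. The comparison addresses what BCAT1 does in leukaemia cells. Each of the 6 groups had 3 arrays, 18 in all, and a single hairpin against BCAT1 was used throughout. All arrays had nearly the same brightness, with median probe intensities between 91.0 and 93.1, and arrays of a group correlated across genes with r between 0.989 and 0.996. The number of arrays limits the precision.

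With the control hairpin, the lines differed in their myeloid genes. Myeloperoxidase (MPO) had a mean intensity of 14290 ± 118 (SD, n = 3) in HL-60, 11690 ± 630 in SKM1 and 684 ± 92.8 in MOLM13. Neutrophil elastase (ELANE) lay at 86.8 ± 5.33 in HL-60, below the median of all probe values of 92.1, but at 8271 ± 203 in SKM1 and 13900 ± 951 in MOLM13. The receptor tyrosine kinase FLT3 was bright in MOLM13 alone among the 3 lines, at 1551 ± 114 against 87.8 ± 5.91 in HL-60 and 183 ± 2.76 in SKM1. Its partner in the stem and progenitor list, the homeobox factor MEIS1, lay at 468 ± 54.2 in MOLM13, 108 ± 22.3 in HL-60 and 109 ± 3.67 in SKM1.

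BCAT1 itself fell in all 3 lines. Its intensity was 145 ± 16.4 (SD, n = 3) with shBCAT1 against 1468 ± 10.9 with shNT in HL-60, 127 ± 6.05 against 1221 ± 16.5 in SKM1, and 157 ± 14 against 1071 ± 64.7 in MOLM13. These are decreases of 10.2-fold, 9.62-fold and 6.84-fold, or log2 fold changes of -3.34, -3.27 and -2.77, each with a standard error (SE) of 0.08 (limma adjusted p = 2.46e-18, 4.20e-18 and 1.64e-16). The decrease differed between lines (F test across the lines, adjusted p = 0.00222). In all 3 lines every shBCAT1 array lay below every shNT array, as 10% of genes do in either direction by chance with 3 arrays against 3. The intensity with shBCAT1 was 9.89%, 10.4% and 14.6% of that with shNT, with no background correction made here. Of the part above the median of all probe values, 3.86%, 3.10% and 6.61% remained.

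**Figure D1:**
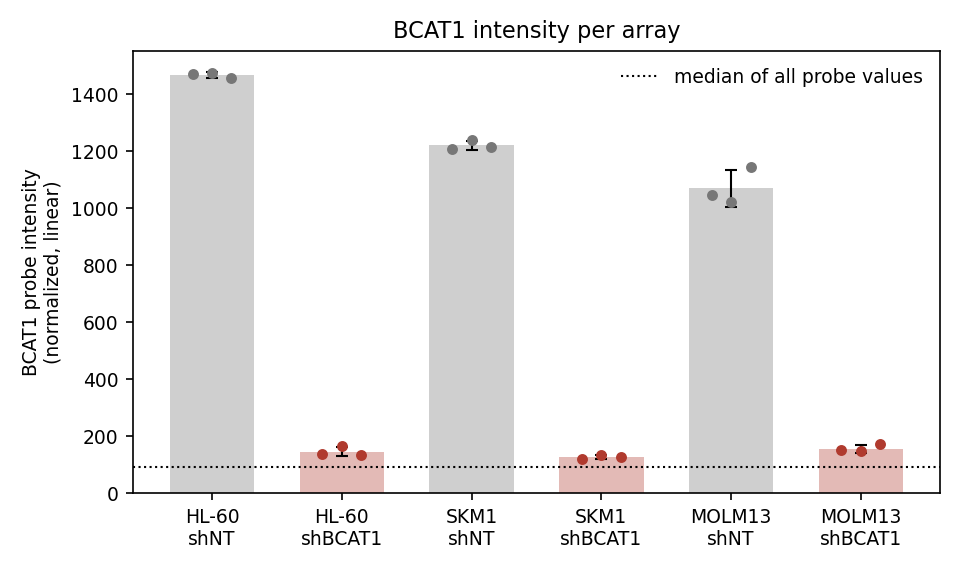
Intensity of the BCAT1 probe (linear, normalized) on each of the 18 arrays, grouped by line and hairpin. Points are arrays, bars are means of 3 arrays, error bars are SD and the dotted line is the median of all probe values, 92.1; the shBCAT1 arrays of the 3 lines average between 127 and 157, the shNT arrays between 1071 and 1468.

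In HL-60, the transcription factor MYC and its targets fell, and genes of autophagy and the lysosome rose. Myeloid differentiation genes rose by camera with the preset correlation, a call that was lost when the correlation was estimated (adjusted p = 0.0545 with an estimated correlation). The Fc receptor gamma chain FCER1G rose 3.24-fold, its relative TYROBP 3.39-fold and the integrin ITGAX 3.34-fold, while MYC fell 2.16-fold (n = 3 arrays per hairpin, SE of the log2 fold changes 0.11 to 0.14). Of 15288 genes tested, 2881 changed in this line, 1525 upward and 1356 downward. At least 1.5-fold changes were fewer, with 391 rises and 272 falls. The shBCAT1 and shNT arrays did not overlap for 28.4% of genes, against the 10% that chance gives.

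The largest measured rise in HL-60 was that of SCG2, a secretogranin of neuroendocrine secretory granules, from an intensity of 91.4 with shNT to 534 with shBCAT1 (5.85-fold, limma adjusted p = 3.20e-16). Its size is uncertain, since the shNT value lay below the median of all probe values. The Src-family kinase FGR rose 5.41-fold, the Notch-modifying glycosyltransferase LFNG 5.13-fold, the stathmin STMN3 3.90-fold and the cytokine TNF 3.87-fold. The galectin LGALS1 and the surface glycoprotein CD52 rose 3.13-fold and 3.11-fold. After BCAT1 the largest falls were those of the cell cycle kinase CDK6 (3.24-fold), the transcription factor BCL11A (3.17-fold), the phosphatase DUSP3 (2.98-fold), the RNA-binding protein LSM14A (2.94-fold) and HADH, an enzyme of mitochondrial fatty acid oxidation (2.74-fold). SPTSSA, a subunit of the enzyme that starts sphingolipid synthesis, fell 2.73-fold, mitochondrial topoisomerase TOP1MT 2.60-fold, the nucleolar protein NOLC1 2.60-fold and stanniocalcin 2 (STC2) 2.55-fold. The log2 fold changes of these 19 genes had SEs of 0.08 to 0.16, and the largest adjusted p among them was 1.27e-06.

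Among the gene lists, 23 of the 33 MYC targets tested fell in HL-60 (25 adjusted over the list alone), with a median log2 fold change of -0.35 (camera adjusted p = 2.72e-12, and adjusted p = 0.00193 with an estimated correlation). NOLC1 (log2 fold change -1.38), lactate dehydrogenase LDHA (-1.11), PPAN (-0.47) and the polyamine enzyme ODC1 (-0.57) led them. Genes of autophagy and the lysosome rose: 18 of 30 were higher and 1 lower (21 and 2 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 5.22e-08, and adjusted p = 0.00193 with an estimated correlation). They included the cathepsins CTSD (1.12), CTSA (0.70) and CTSZ (0.79) and the autophagy receptor SQSTM1 (1.06). In the type I interferon response, 14 of 36 members rose (15 adjusted over the list alone, where 1 also fell), with the regulators IRF9 (1.31) and IRF7 (0.84) and SAMD9L (0.74) in front (camera adjusted p = 1.51e-06, and adjusted p = 0.0236 with an estimated correlation). Of 24 members of the NF-kB and inflammatory list, 10 rose (10 adjusted over the list alone), among them TNF (1.95), IER3 (1.09) and TNFAIP2 (0.79) (camera adjusted p = 6.96e-05, and adjusted p = 0.0499 with an estimated correlation).

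The other lists called in HL-60 were not called with an estimated correlation. Of 32 myeloid differentiation genes, 14 rose (14 adjusted over the list alone), with FCER1G, TYROBP and ITGAX as above and the Fc receptor FCGR2A (1.29) (camera adjusted p = 2.30e-09, and adjusted p = 0.0545 with an estimated correlation). Mitosis and G2/M genes had 15 rises among 32 members (17 adjusted over the list alone), led by DLGAP5 (0.59), KIF20A (0.47) and HMMR (0.56) (camera adjusted p = 1.78e-06, and adjusted p = 0.311 with an estimated correlation). Of 37 targets of ATF4, the transcription factor of the amino acid response, 18 fell and 1 rose (20 and 1 adjusted over the list alone), with STC2 (-1.35) and the lipoprotein receptor VLDLR (-0.61) among the falls (camera adjusted p = 1.24e-06, and adjusted p = 0.311 with an estimated correlation). Of 36 targets of the hypoxia factor HIF1, 11 fell and 3 rose (12 and 4 adjusted over the list alone), LDHA (-1.11) and ALDOC (-0.99) falling and PFKFB3 (0.55) rising (camera adjusted p = 0.00210, and adjusted p = 0.458 with an estimated correlation). Glycolysis, which shares members with that list, had 5 falls and 1 rise among 19 (6 and 2 adjusted over the list alone); hexokinase HK2 (-0.79) fell and the glucose carrier SLC2A3 (0.93) rose (camera adjusted p = 0.00773, and adjusted p = 0.347 with an estimated correlation).

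DNA replication and G1/S genes in HL-60 had 8 falls and 2 rises among 33 (12 and 2 adjusted over the list alone), with UNG (-0.60) and MCM3 (-0.39) lower and RRM2 (0.49) higher (camera adjusted p = 0.00524, and adjusted p = 0.614 with an estimated correlation). Of 30 immediate early genes, 9 rose and 3 fell (13 and 3 adjusted over the list alone): cyclin D1 (CCND1, 1.42) and PHLDA1 (1.36) were higher, MYC (-1.11) lower (camera adjusted p = 0.0104, and adjusted p = 0.424 with an estimated correlation). The heat shock and proteasome list had 5 rises and 1 fall among 24 (7 and 1 adjusted over the list alone), with the inducible HSPA1B (1.30) higher and HSP90AB1 (-1.22) lower (camera adjusted p = 0.0269, and adjusted p = 0.424 with an estimated correlation). The value of HSPA1B is uncertain because of its near-identical neighbour HSPA1A. Without shBCAT1 replicate 3 the call of the replication list ended (adjusted p = 0.142), without shNT replicate 3 that of the immediate early list (0.0672), and without shBCAT1 replicate 1 or 2 that of the heat shock list (0.0777 and 0.138), which a stricter filter on dim genes also ended (0.0683).

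In SKM1, genes of granule proteins fell. HIF1 targets and glycolysis genes fell by camera with the preset correlation, and both calls were lost when it was estimated (adjusted p = 0.138 and 0.121 with an estimated correlation). Proteoglycan 2 (PRG2), best known from the granules of eosinophils, fell 5.48-fold, from an intensity of 1171 to 214. In the same line myeloperoxidase (MPO) fell 4.70-fold, from 11690 to 2498, and the glycolytic regulator PFKFB4 fell 4.92-fold (n = 3 arrays per hairpin, SE of the log2 fold changes 0.08, 0.10 and 0.25). ALOX5AP, which presents arachidonic acid to the enzyme of leukotriene synthesis, rose 4.54-fold. In all, 1704 genes changed in this line, 712 upward and 992 downward, and at least 1.5-fold changes numbered 116 rises and 265 falls. The arrays of the hairpins did not overlap for 33.3% of genes, against 10% by chance. The count depends on how the spread is estimated, because SKM1 arrays varied less than those of the other lines. It was 3098 with array weights and 3000 in a fit of the SKM1 arrays alone. Fits of the arrays of 1 line gave 2094 changed genes in HL-60 and 2541 in MOLM13. The order of the lines by count therefore depends on the fit.

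The other largest rises in SKM1 were those of FGR (3.13-fold), annexin ANXA1 (2.95-fold), the immunoglobulin M receptor FCMR (2.70-fold), LFNG (2.48-fold) and the costimulatory receptor CD86 (2.46-fold). The protease inhibitor TIMP1 rose 2.43-fold, the histone-modifying deiminase PADI4 2.42-fold, the chemokine CXCL8 2.36-fold and synaptophysin (SYP), a membrane protein of neuronal vesicles, 2.35-fold from a value near the median of all probe values, which leaves its size uncertain. Falls included BCL11A (3.44-fold), BEND5 (3.12-fold), the splicing protein SNRNP27 (3.06-fold), TOP1MT (3.05-fold), TMEM45A (3.01-fold) and CDK6 (2.93-fold). Over these 19 genes the SEs were 0.08 to 0.25 and the largest limma adjusted p was 0.000363.

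Of 18 neutrophil granule proteins tested in SKM1, 8 fell and 1 rose (10 and 2 adjusted over the list alone), with a median log2 fold change of -0.35 (camera adjusted p = 2.63e-09, and adjusted p = 0.000516 with an estimated correlation). The serine proteases PRTN3 (-1.52) and ELANE (-1.07) fell with MPO (-2.23) and PRG2 (-2.45). This was the single list of the 32 that held in SKM1 with an estimated correlation. HIF1 targets followed, with 14 falls and 1 rise among 36 (21 and 1 adjusted over the list alone), among them TMEM45A (-1.59), PFKFB4 (-2.30) and ALDOC (-1.05) (camera adjusted p = 3.59e-11, and adjusted p = 0.138 with an estimated correlation). Of 19 glycolysis genes, 6 fell (11 adjusted over the list alone), including LDHA (-0.91), HK2 (-0.83) and glucose-6-phosphate isomerase GPI (-0.79) (camera adjusted p = 3.31e-07, and adjusted p = 0.121 with an estimated correlation). In the NF-kB and inflammatory list 7 of 24 rose (8 adjusted over the list alone), led by IL1B (1.03), TNF (0.97) and PTGS2 (0.56) (camera adjusted p = 8.97e-05, and adjusted p = 0.0907 with an estimated correlation).

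Other lists in SKM1 were called by camera with the preset correlation and not with an estimated one. Of 33 oxidative phosphorylation genes 2 rose (2 adjusted over the list alone), one of them UQCRB (0.41), with a median of 0.13 (camera adjusted p = 0.000255, and adjusted p = 0.242 with an estimated correlation). Of 33 MYC targets 5 fell (6 adjusted over the list alone), with NOLC1 (-1.16) and ODC1 (-0.38) among them (camera adjusted p = 0.0287, and adjusted p = 0.242 with an estimated correlation). The endoplasmic reticulum unfolded protein response had 3 falls among 24 (4 adjusted over the list alone), led by the chaperones CANX (-1.28) and CALR (-0.49) (camera adjusted p = 0.0300, and adjusted p = 0.258 with an estimated correlation). In the type I interferon list 5 members rose and 1 fell among 36 (7 and 1 adjusted over the list alone), MX2 (0.53) rising and HERC5 (-0.77) falling (camera adjusted p = 0.0336, and adjusted p = 0.242 with an estimated correlation). Heat shock and proteasome genes had 4 rises and 1 fall among 24 (5 and 1 adjusted over the list alone), with DNAJB1 (0.52) up and HSP90AB1 (-1.26) down (camera adjusted p = 0.0259, and adjusted p = 0.366 with an estimated correlation). The DNA methylation machinery had 3 falls and 1 rise among 13 (5 and 1 adjusted over the list alone). DNMT3L (-0.62) and the maintenance methyltransferase DNMT1 (-0.43) were lower (camera adjusted p = 0.0404, and adjusted p = 0.138 with an estimated correlation). Myeloid differentiation genes went both ways, 10 rising and 4 falling among 32 (10 and 5 adjusted over the list alone): CD86 (1.30) and the integrin ITGAM (0.98) rose, the monocyte factor IRF8 (-1.36) and receptor CSF1R (-1.13) fell (camera adjusted p = 0.0440, and adjusted p = 0.484 with an estimated correlation).

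Leaving out 1 array ended some of these SKM1 list calls. Without shNT replicate 1 the adjusted p was 0.0971 for the unfolded protein response and 0.0665 for the heat shock, myeloid differentiation and DNA methylation lists, and without shNT replicate 2 it was 0.0518 for the interferon and myeloid differentiation lists. Without shBCAT1 replicate 1 it was 0.0522 for myeloid differentiation and 0.0542 for DNA methylation, without shBCAT1 replicate 2 it was 0.0511 for the interferon list, and without shBCAT1 replicate 3 it was 0.0540 for myeloid differentiation and DNA methylation. A stricter filter on dim genes gave 0.0689 for the MYC, unfolded protein response and myeloid differentiation lists.

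In MOLM13, genes of DNA replication and of mitosis fell broadly, and with them HIF1 targets and glycolysis genes, while lysosome genes and targets of p53 rose. Falls of cholesterol synthesis and ATF4 targets and a rise of myeloid differentiation genes were called with the preset correlation and lost when it was estimated (adjusted p = 0.146, 0.102 and 0.0512 with an estimated correlation). The replicative helicase subunit MCM2 fell 3.15-fold and the aldolase ALDOC 3.41-fold, while the calcium-binding protein S100A8 rose 4.42-fold and the stress-response gene TP53INP1 3.07-fold (n = 3 arrays per hairpin, SE of the log2 fold changes 0.10 to 0.14). Of the genes tested, 3208 changed in this line, 1570 upward and 1638 downward. At least 1.5-fold changes numbered 331 rises and 448 falls, and the arrays of the hairpins did not overlap for 31.0% of genes, against 10% by chance.

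STMN3 rose most, 4.61-fold, followed by S100A8, the chemokine CCL2 (4.04-fold), the chemokine receptor CX3CR1 (4.03-fold), the cholesterol exporter ABCA1 (3.81-fold) and haptoglobin HP (3.63-fold). The lysosomal enzymes FUCA1 and DNASE2 rose 3.43-fold and 3.13-fold, and the metalloprotease ADAMDEC1 3.26-fold. Apart from BCAT1 and ALDOC, the largest measured falls included those of the kinase PNCK (5.17-fold), the signalling regulator RGS16 (3.51-fold), the pseudogene SLC6A10P (3.49-fold), neuronal enolase ENO2 (3.45-fold) and the non-coding RNA LINC03040 (3.36-fold). RGCC, a cell cycle regulator, fell 3.30-fold, the immediate early factor EGR1 3.27-fold and the mitophagy receptor BNIP3 3.24-fold. The SEs of these 19 genes were 0.08 to 0.30 and the largest limma adjusted p was 9.31e-05. The sizes of the PNCK and SLC6A10P falls are uncertain, since both ended near the median of all probe values, and the sequence of SLC6A10P also resembles that of its parent gene SLC6A8.

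Of 33 DNA replication and G1/S genes in MOLM13, 27 fell (29 adjusted over the list alone), with a median log2 fold change of -0.84 (camera adjusted p = 2.68e-29, and adjusted p = 0.0319 with an estimated correlation). MCM2 (-1.66), MCM4 (-1.40), E2F2 (-1.26) and CDC25A (-1.06) led. Of 32 mitosis and G2/M genes, 28 fell (30 adjusted over the list alone), including PRC1 (-0.85) and the motor proteins KIF11 (-1.09) and KIF2C (-1.02), with a median of -0.60 (camera adjusted p = 8.42e-24, and adjusted p = 0.0225 with an estimated correlation). HIF1 targets had 24 falls and 1 rise among 36 (27 and 1 adjusted over the list alone), with ALDOC (-1.77), ENO2 (-1.79), ZNF395 (-1.63) and LDHA (-1.20) in front (camera adjusted p = 1.31e-14, and adjusted p = 0.0421 with an estimated correlation). Of 19 glycolysis genes 11 fell (12 adjusted over the list alone), HK2 (-0.99) among them (camera adjusted p = 3.58e-09, and adjusted p = 0.0319 with an estimated correlation). MYC targets had 21 falls among 33 (22 adjusted over the list alone). PA2G4 (-0.48) and NOP56 (-0.57) were among them (camera adjusted p = 3.69e-09, and adjusted p = 0.00664 with an estimated correlation). In the DNA methylation machinery 5 of 13 fell and 1 rose (5 and 1 adjusted over the list alone): UHRF1 (-1.08) and DNMT1 (-0.71) were lower, GADD45A (0.65) higher (camera adjusted p = 0.00707, and adjusted p = 0.0421 with an estimated correlation).

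Rising lists in MOLM13 that held with an estimated correlation were those of the lysosome, p53 and histones. Autophagy and lysosome genes had 18 rises and 1 fall among 30 (22 and 1 adjusted over the list alone). CTSD (1.24), the proton pump subunit ATP6V0D1 (1.21) and GABARAPL1 (1.10) were among them (camera adjusted p = 1.00e-10, and adjusted p = 0.000858 with an estimated correlation). Of 26 p53 targets 13 rose (14 adjusted over the list alone, where 2 also fell), led by SESN1 (1.13), TP53INP1 (1.62) and RRM2B (0.75) (camera adjusted p = 1.19e-06, and adjusted p = 0.00162 with an estimated correlation). Of 16 histone genes 7 rose and 2 fell (10 and 2 adjusted over the list alone), H2AC6 (1.08) and H2BC5 (0.79) rising and H4C3 (-0.62) falling (camera adjusted p = 0.00177, and adjusted p = 0.0421 with an estimated correlation).

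A further 12 lists were called in MOLM13 with the preset correlation and not with an estimated one. ATF4 targets had 25 falls and 1 rise among 37 (25 and 1 adjusted over the list alone): the amino acid carriers SLC7A1 (-1.11) and SLC7A5 (-0.96) and the serine synthesis enzyme PHGDH (-1.0) fell (camera adjusted p = 8.31e-10, and adjusted p = 0.102 with an estimated correlation). Of 20 genes of cholesterol synthesis and uptake 13 fell (14 adjusted over the list alone). DHCR7 (-1.51) and FDPS (-1.10) were among them (camera adjusted p = 6.35e-08, and adjusted p = 0.146 with an estimated correlation). Fatty acid synthesis had 10 falls and 2 rises among 17 (11 and 2 adjusted over the list alone), FASN (-1.01) and ACACA (-0.78) falling (camera adjusted p = 0.000167, and adjusted p = 0.124 with an estimated correlation). Myeloid differentiation genes had 17 rises and 1 fall among 32 (18 and 1 adjusted over the list alone). S100A8 (2.15), CD86 (1.41) and the endotoxin receptor TLR4 (0.64) were among them (camera adjusted p = 4.28e-08, and adjusted p = 0.0512 with an estimated correlation). Of 36 interferon response genes 13 rose and 2 fell (13 and 2 adjusted over the list alone). TRIM22 (0.94) and IRF9 (0.61) were among them (camera adjusted p = 0.00177, and adjusted p = 0.0697 with an estimated correlation). In the NRF2 and oxidative stress list 7 of 20 rose (7 adjusted over the list alone), AKR1C3 (1.39) and haem oxygenase HMOX1 (0.93) most clearly (camera adjusted p = 0.00177, and adjusted p = 0.134 with an estimated correlation). Oxidative phosphorylation had 7 rises among 33 (9 adjusted over the list alone), cytochrome c (CYCS, 0.53) and NDUFB5 (0.43) among them (camera adjusted p = 0.00143, and adjusted p = 0.157 with an estimated correlation).

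Branched-chain amino acid catabolism, the pathway that BCAT1 opens, rose as a list in MOLM13, with 6 of 23 members higher (7 adjusted over the list alone). HSD17B10 (0.53), HIBADH (0.47) and PCCA (0.47) led (camera adjusted p = 0.0123, and adjusted p = 0.0803 with an estimated correlation). Of 23 genes of glutamate, glutamine and alpha-ketoglutarate metabolism 9 fell and 1 rose (9 and 2 adjusted over the list alone): the glutamine carrier SLC1A5 (-0.95), IDH2 (-0.65) and PSAT1 (-0.79) fell (camera adjusted p = 0.0200, and adjusted p = 0.0593 with an estimated correlation). Immediate early genes had 9 falls and 1 rise among 30 (9 and 1 adjusted over the list alone), CCND1 (-1.13) and the ETS factors ETV4 (-0.73) and ETV5 (-0.87) falling (camera adjusted p = 7.78e-05, and adjusted p = 0.124 with an estimated correlation). Of 18 granule proteins 6 rose and 1 fell (7 and 1 adjusted over the list alone), with the antimicrobial peptide CAMP (1.39) higher and MPO (-0.93) lower (camera adjusted p = 0.0281, and adjusted p = 0.0657 with an estimated correlation). The size of the CAMP rise is uncertain, since its shNT intensity of 106.5 lay near the median of all probe values. Heat shock and proteasome genes had 6 falls and 1 rise among 24 (6 and 1 adjusted over the list alone). HSP90AB1 (-1.33) and PSMD12 (-0.44) were lower (camera adjusted p = 0.0315, and adjusted p = 0.333 with an estimated correlation). The granule call ended without shBCAT1 replicate 3 (adjusted p = 0.0609), and the heat shock call without shBCAT1 replicate 1 (0.0931), shNT replicate 2 (0.0616) or shNT replicate 3 (0.0875) and with the mean of a gene's probes (0.0958). Both ended under a stricter filter on dim genes (0.0835).

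**Figure D2:**
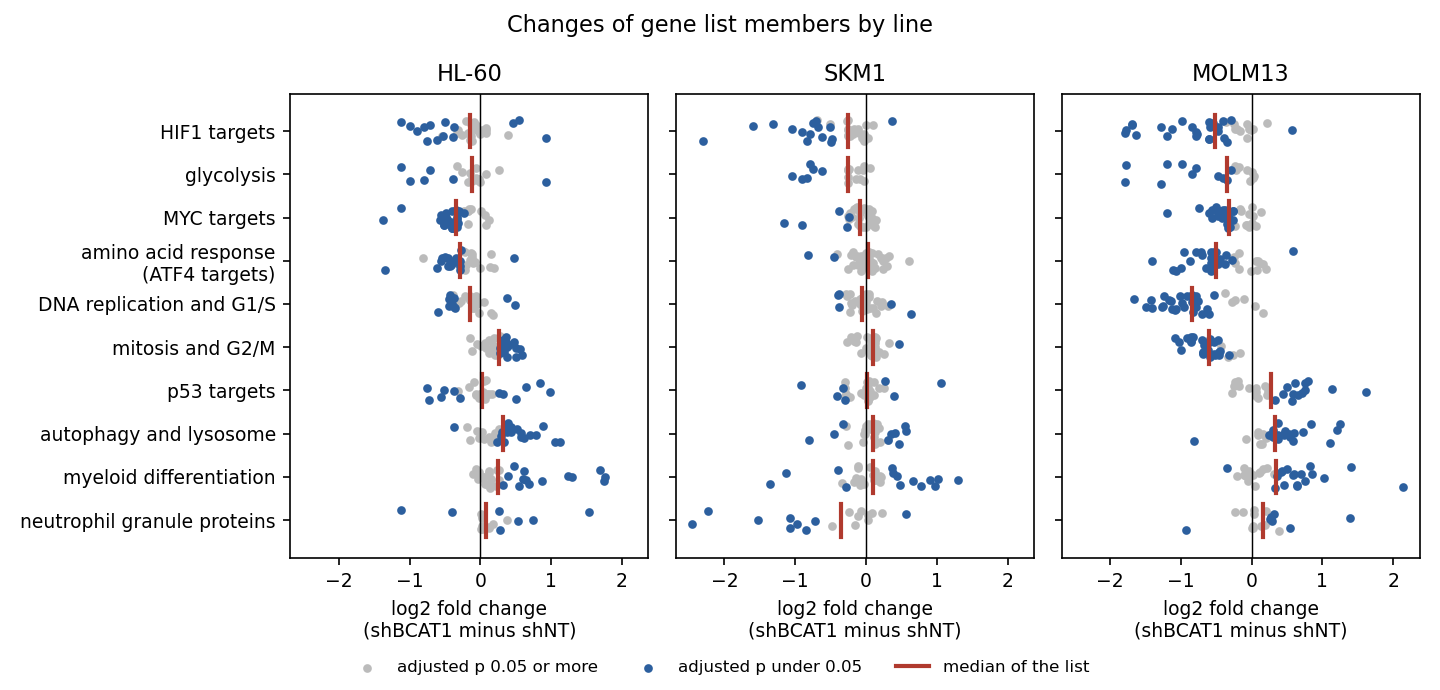
Log2 fold changes (shBCAT1 minus shNT, from 3 arrays per hairpin) of the tested members of 10 gene lists in each line. Each point is a gene, blue when its adjusted p is under 0.05, and the red bar is the median of the list; the replication and mitosis medians lie at -0.84 and -0.60 in MOLM13, and the mitosis median at 0.26 in HL-60.

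Across the 3 lines taken with equal weight, genes of the lysosome and the interferon response rose, and MYC targets fell. The lysosome list was called in HL-60 and MOLM13 and not in SKM1 (camera adjusted p = 0.0748). A rise of myeloid differentiation genes and falls of glycolysis and replication genes were called with the preset correlation and lost when it was estimated (adjusted p = 0.0550, 0.0550 and 0.109 with an estimated correlation). FGR rose 3.17-fold in the mean of the lines, TYROBP 2.26-fold and the costimulatory receptor CD86 2.15-fold, while PFKFB4 fell 3.00-fold, CDK6 2.57-fold and ALDOC 2.41-fold (9 arrays per hairpin, SE of the log2 fold changes 0.06 to 0.14). The errors and p-values of the mean measure the spread between arrays of a group, not the spread between lines. In all 4263 genes changed in the mean, 2114 upward and 2149 downward, of which 120 rose and 161 fell at least 1.5-fold. STMN3 (3.09-fold), LFNG (2.47-fold), GLIPR1 (2.19-fold, with shNT near the median of all probe values in HL-60), the T-cell inhibitory ligand VSIR (2.18-fold), the integrin ITGB7 (2.16-fold), ANXA1 (2.16-fold) and ALOX5AP (2.03-fold) completed the largest rises. Some of these rises were uneven. In HL-60, SKM1 and MOLM13 the log2 fold changes of LFNG were 2.36, 1.31 and 0.23 (F test adjusted p = 9.30e-07). Those of ALOX5AP were 0.69, 2.18 and 0.19 (6.54e-10). TOP1MT (2.65-fold), BCL11A (2.51-fold), BNIP3 (2.47-fold), the vesicle protein SCAMP1 (2.46-fold), HADH (2.46-fold) and the chaperone HSP90AB1 (2.41-fold) completed the largest falls after BCAT1. The largest limma adjusted p among these 19 genes was 7.08e-09. Fall sizes of HSP90AB1 were nearly equal in the lines, with log2 fold changes of -1.22 in HL-60, -1.26 in SKM1 and -1.33 in MOLM13 (SE 0.10 in each).

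Of the 17 lists called in the mean, 3 held with an estimated correlation. MYC targets had 24 falls among 33 (24 adjusted over the list alone), with PA2G4 (-0.33) and ODC1 (-0.45) (camera adjusted p = 1.16e-11, and adjusted p = 0.00292 with an estimated correlation). Autophagy and lysosome genes had 20 rises and 1 fall among 30 (22 and 2 adjusted over the list alone). CTSD (0.98) and ATP6V0D1 (0.88) were among the rises (camera adjusted p = 7.42e-10, and adjusted p = 0.00131 with an estimated correlation). The interferon response had 16 rises and 1 fall among 36 (17 and 1 adjusted over the list alone). IRF9 (0.74), IFI35 (0.54) and IFI6 (0.47) rose (camera adjusted p = 5.13e-06, and adjusted p = 0.0368 with an estimated correlation). HIF1 targets had 26 falls and 1 rise among 36 (28 and 1 adjusted over the list alone), with HK2 (-0.87) and LDHA (-1.07) (camera adjusted p = 1.43e-13, and adjusted p = 0.0550 with an estimated correlation). Of 19 glycolysis genes 11 fell in the mean (13 adjusted over the list alone), GPI (-0.66) among them (camera adjusted p = 2.59e-08, and adjusted p = 0.0550 with an estimated correlation). Replication genes had 25 falls among 33 (25 adjusted over the list alone), with MCM2 (-0.82) and MCM3 (-0.60) (camera adjusted p = 1.06e-13, and adjusted p = 0.109 with an estimated correlation). Of 32 myeloid differentiation genes 18 rose and 1 fell (18 and 1 adjusted over the list alone). ITGAM (0.82) and FCER1G (0.89) were among the rises (camera adjusted p = 1.26e-08, and adjusted p = 0.0550 with an estimated correlation).

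The remaining lists were called in the mean with the preset correlation and not with an estimated one. ATF4 targets had 23 falls and 1 rise (26 and 1 adjusted over the list alone), with VLDLR (-0.71) and SLC7A1 (-0.55) (camera adjusted p = 7.04e-08, and adjusted p = 0.201 with an estimated correlation). The NF-kB list had 11 rises (11 adjusted over the list alone, where 2 also fell), with IL1B (0.76) and TNF (0.84) (camera adjusted p = 0.000212, and adjusted p = 0.0550 with an estimated correlation). Cholesterol synthesis and uptake had 14 falls and 1 rise (14 and 1 adjusted over the list alone), with LSS (-0.76) and DHCR7 (-0.74) (camera adjusted p = 0.000394, and adjusted p = 0.405 with an estimated correlation). Oxidative phosphorylation had 10 rises and 1 fall (12 and 1 adjusted over the list alone), with CYCS (0.27) and UQCRB (0.28) (camera adjusted p = 0.000796, and adjusted p = 0.201 with an estimated correlation). The NRF2 list had 10 rises and 2 falls (11 and 2 adjusted over the list alone). SQSTM1 (0.63) and HMOX1 (0.50) rose (camera adjusted p = 0.00678, and adjusted p = 0.220 with an estimated correlation). Mitosis genes had 12 falls and 1 rise (14 and 1 adjusted over the list alone), with KIF11 (-0.39) (camera adjusted p = 0.0144, and adjusted p = 0.520 with an estimated correlation).

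Glutamate, glutamine and alpha-ketoglutarate metabolism had 9 falls and 3 rises in the mean (9 and 3 adjusted over the list alone). ALDH18A1 (-0.47) and SLC1A5 (-0.51) fell (camera adjusted p = 0.0144, and adjusted p = 0.0550 with an estimated correlation). The DNA methylation machinery had 5 falls (5 adjusted over the list alone), with DNMT1 (-0.40) and UHRF1 (-0.49) (camera adjusted p = 0.0194, and adjusted p = 0.0613 with an estimated correlation). Fatty acid synthesis had 10 falls and 5 rises (11 and 5 adjusted over the list alone). ACLY (-0.61) fell (camera adjusted p = 0.0226, and adjusted p = 0.405 with an estimated correlation). The p53 list had 10 rises and 4 falls (11 and 6 adjusted over the list alone), with the death receptor TNFRSF10B (0.65) and CDKN1A (0.70) rising and RPS27L (-0.62) falling (camera adjusted p = 0.0299, and adjusted p = 0.0623 with an estimated correlation). A stricter filter on dim genes ended the fatty acid call (adjusted p = 0.0641) and the p53 call (0.0749).

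Among the lists closest to the reaction of BCAT1, camera called neither branched-chain catabolism nor the dioxygenases nor the tricarboxylic acid cycle in the mean. Of 23 genes of branched-chain amino acid catabolism 6 rose and 4 fell (6 and 4 adjusted over the list alone), DBT (0.40) rising and BCKDHA (-0.37), both parts of the branched-chain ketoacid dehydrogenase, falling (camera adjusted p = 0.419, and adjusted p = 0.541 with an estimated correlation). Of 36 dioxygenases that use alpha-ketoglutarate 13 fell and 4 rose (13 and 4 adjusted over the list alone), with the collagen hydroxylase P4HA1 (-0.54) lower and ALKBH3 (0.35) higher (camera adjusted p = 0.0529, and adjusted p = 0.201 with an estimated correlation). By fry, which does not compare a list with other genes, the dioxygenases shifted downward on balance (adjusted p = 0.000576) and branched-chain catabolism was not past the test (adjusted p = 0.0612). The tricarboxylic acid cycle had 3 falls and 1 rise among 20 (1 and 0 adjusted over the list alone), with SUCLA2 lower (-0.50) (camera adjusted p = 0.516, and adjusted p = 0.761 with an estimated correlation).

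The lists that camera did not call in the mean still held single changed genes. Of 18 apoptosis regulators of the BCL2 family 7 rose and 3 fell (7 and 3 adjusted over the list alone): the survival protein MCL1 rose (0.52), BCL2 (-0.80) and BNIP3 (-1.30) fell (adjusted p = 0.333, or adjusted p = 0.523 with an estimated correlation). Of 20 stem and progenitor genes 5 fell and 2 rose (6 and 3 adjusted over the list alone). MYB (-0.47) and FLT3 (-0.22) were among the falls (adjusted p = 0.485, or adjusted p = 0.541 with an estimated correlation). Granule proteins had 7 falls and 4 rises among 18 (7 and 5 adjusted over the list alone), MPO (-1.05) lower and CAMP (0.56) higher (adjusted p = 0.419, or adjusted p = 0.493 with an estimated correlation). The size of the CAMP change is uncertain, since its shNT values lay near or below the median of all probe values. The unfolded protein response had 3 rises and 3 falls among 24 (3 and 3 adjusted over the list alone), with CANX lower (-1.03) (adjusted p = 0.734, or adjusted p = 0.846 with an estimated correlation). Immediate early genes had 6 rises and 4 falls among 30 (6 and 4 adjusted over the list alone), with PHLDA1 (0.59) higher and DUSP5 (-0.63) lower (adjusted p = 0.816, or adjusted p = 0.903 with an estimated correlation). Heat shock and proteasome genes had 7 rises and 2 falls among 24 (9 and 2 adjusted over the list alone), HSPH1 (0.24) among the rises (adjusted p = 0.208, or adjusted p = 0.541 with an estimated correlation).

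Histone genes had 5 rises and 2 falls in the mean among 16 (5 and 2 adjusted over the list alone), with H2BC5 higher (0.59) (adjusted p = 0.0920, or adjusted p = 0.226 with an estimated correlation). Cytosolic ribosomal proteins stayed within a narrow range, 3 rising and 1 falling among 33 (1 and 0 adjusted over the list alone), RPL37 (0.28) among the rises (adjusted p = 0.960, or adjusted p = 0.973 with an estimated correlation). Of 12 genes of microRNA and shRNA processing, 4 fell and 3 rose (5 and 3 adjusted over the list alone). DROSHA (-0.41) and AGO2 (-0.39) were lower (adjusted p = 0.531, or adjusted p = 0.541 with an estimated correlation). Markers of other cells that a culture might hold were not called as lists by camera in any line. By fry, the lymphoid list was called upward in HL-60 (adjusted p = 0.00113) and in the mean (0.00545), and the erythroid and megakaryocytic list downward in MOLM13 (0.00159). The erythroid and megakaryocytic list had 1 fall among 13 in the mean (EPOR, -0.38; 1 adjusted over the list alone; adjusted p = 0.826, or adjusted p = 0.846 with an estimated correlation). The lymphoid list had 1 rise (NKG7, 0.33) and 1 fall among 12 (1 and 1 adjusted over the list alone; adjusted p = 0.419, or adjusted p = 0.496 with an estimated correlation), and the epithelial and packaging cell list 1 rise among 11 (TPM1, 0.27; 1 adjusted over the list alone; adjusted p = 0.843, or adjusted p = 0.884 with an estimated correlation).

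The changes were partly shared between lines. Of 5413 genes called in at least 1 line, 199 rose in all 3 and 244 fell in all 3, where independent lists would give 7.29 and 9.43. HL-60 and SKM1 had 387 rises and 447 falls in common (71.0 and 88.0 for independent lists), HL-60 and MOLM13 507 and 487 (157 and 145), and SKM1 and MOLM13 331 and 390 (73.1 and 106). Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.477 between HL-60 and SKM1, 0.311 between HL-60 and MOLM13 and 0.363 between SKM1 and MOLM13. Genes called in opposite directions numbered 36, 203 and 88 for the same pairs. Each line had its own shNT arrays, so no control is shared between the comparisons.

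**Figure D3:**
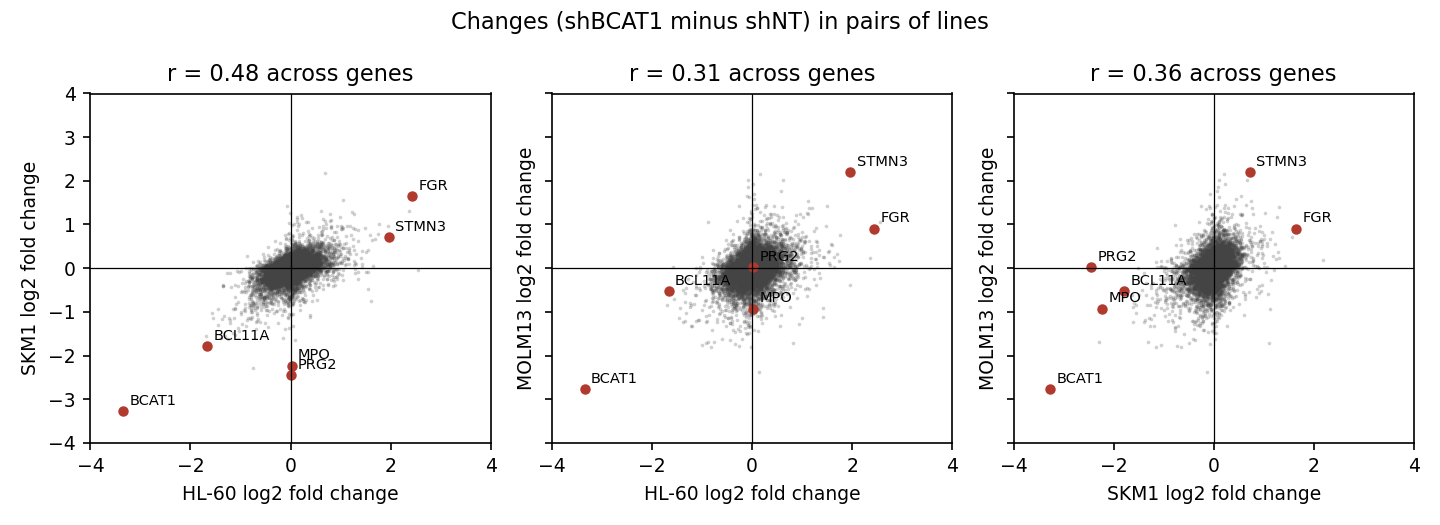
Log2 fold changes (shBCAT1 minus shNT) of all 15288 tested genes in pairs of lines, 1 point per gene and 6 genes marked in red. The points correlate with r = 0.477, 0.311 and 0.363 across genes, BCAT1 lies low in every panel, and PRG2 and MPO lie low in SKM1 and near 0 in HL-60.

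The lines also differed in their response, which was tested directly with an F test of the differences between the 3 changes. The eosinophil granule protein PRG2 fell in SKM1 (log2 fold change -2.45), with values of 0.02 in HL-60 and 0.02 in MOLM13, where it was more than 10 times as bright. CCND1, which drives entry into the cell cycle, rose in HL-60 (1.42), was 0.09 in SKM1 and fell in MOLM13 (-1.13). MPO fell in SKM1 (-2.23) and MOLM13 (-0.93) and was 0.02 in HL-60. The receptor CSF1R fell in SKM1 (-1.13) and rose in HL-60 (0.39) and MOLM13 (0.45), and the urokinase receptor PLAUR rose in HL-60 (1.11) and SKM1 (0.45) and fell in MOLM13 (-0.63). SCG2 rose in HL-60 (2.55) and MOLM13 (1.05) and was -0.03 in SKM1, ADAMDEC1 rose in MOLM13 (1.71), ALOX5AP and FCMR rose most in SKM1 (2.18 and 1.43), and STMN3 rose in all 3 lines (1.96, 0.72 and 2.20).

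The F test called 2741 genes, 17.9% of those tested, and the adjusted p of these 10 genes ranged from 6.48e-13 for PRG2 to 5.90e-09 for STMN3 (n = 3 arrays per group, limma). Pairwise, 977 genes differed between SKM1 and HL-60, 2226 between MOLM13 and HL-60 and 1546 between MOLM13 and SKM1. Mitosis genes were lower in MOLM13 than in HL-60 by a median of -0.90 (adjusted p = 7.03e-31, and adjusted p = 0.0167 with an estimated correlation) and lower than in SKM1 by -0.71 (adjusted p = 3.53e-29, and adjusted p = 0.0107 with an estimated correlation). Replication genes differed by -0.77 from HL-60 (adjusted p = 1.73e-18, and adjusted p = 0.150 with an estimated correlation) and by -0.93 from SKM1 (adjusted p = 3.84e-31, and adjusted p = 0.0220 with an estimated correlation). The change of the p53 list was higher in MOLM13 than in HL-60 by 0.31 (adjusted p = 2.14e-05, and 0.00764 with an estimated correlation). It was higher than in SKM1 by 0.36 (adjusted p = 3.19e-07, and adjusted p = 0.000857 with an estimated correlation). The change of granule proteins was lower in SKM1 than in HL-60 by -0.42 (adjusted p = 1.65e-13, and 6.67e-05 with an estimated correlation). In MOLM13 it was higher than in SKM1 by 0.84 (adjusted p = 1.07e-14, and adjusted p = 5.10e-05 with an estimated correlation). MYC targets were less lowered in SKM1 than in HL-60, by 0.26 (adjusted p = 1.47e-07, and adjusted p = 0.0112 with an estimated correlation). Camera did not call autophagy and lysosome genes in SKM1 (adjusted p = 0.0748). Their change was lower there than in HL-60 by -0.29 (adjusted p = 1.43e-05, and adjusted p = 0.00969 with an estimated correlation). In MOLM13 it was higher than in SKM1 by 0.27 (adjusted p = 5.20e-07, and adjusted p = 0.00251 with an estimated correlation). The change of histone genes was higher in MOLM13 than in SKM1 by 0.39 (adjusted p = 0.000138, and 0.0209 with an estimated correlation). The granule differences are limited at both ends of the scale. With shNT, ELANE, CAMP, LTF, LCN2 and MMP9 in HL-60, LCN2 in SKM1, and LTF, LCN2 and MMP8 in MOLM13 lay below the median of all probe values. PRG2 in HL-60 and MOLM13 and MPO in HL-60 lay near the top, between 13490 and 14510. In MOLM13 with shNT, ELANE lay at 13900 and SRGN at 14590, and AZU1, PRTN3 and RNASE2 between 11090 and 12200. ALOX5AP with shNT lay at 7677 in HL-60 and 10730 in MOLM13, against 390 in SKM1, so a limit at the top is not excluded for its difference. Of the genes named for the F test, CCND1 and SCG2 in SKM1, ADAMDEC1 in HL-60 and SKM1 and FCMR in HL-60 lay below that median with both hairpins, where a fall could not be measured.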

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

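The tests of normalization by matched genes, of replicate numbers as a block, of off-target repression and of other probes were chosen only after the results they bear on had been seen.

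Cell cycle genes moved apart between MOLM13 and HL-60. The changes of the 65 tested members of the replication and mitosis lists had a median difference (MOLM13 minus HL-60) of -0.83 on the log2 scale. For 62 of them the change was lower in MOLM13 (camera p = 2.23e-40, p = 0.00195 with an estimated correlation). The tables argue against an intensity-wise effect of normalization, since 20 genes matched in intensity to each member had a median of -0.0294 (sets with 1 match per member -0.13 to 0.11), and against a single array, since the members stayed at -0.78 or lower in 12 fits that each left out 1 array. Replicate numbers vary together in MOLM13, and with the number as a block camera gave p = 4.35e-42 (n = 65 members), but such pairing can only widen the error of a fit without the block, so this decides nothing. What makes the lines differ here stays open: neither their biology nor the depth of the BCAT1 fall, which also differed between lines, was tested as the cause.

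The genes that fell in all 3 lines raise the question of whether the hairpin also represses other transcripts. Among 31 genes that changed at least 1.5-fold the same way in all 3 lines with no difference between lines (F test p of 0.05 or more), 21 fell and 10 rose, HSP90AB1, LDHA and ZDHHC9 among the falls. The share of falls, 67.7% (exact binomial 95% interval 48.6 to 83.3), does not decide: off-target repression by the single hairpin could add to it, and this remains open with 1 hairpin. Of all 244 genes that fell in the 3 lines, 75 had another bright probe. Of these 99 probes, 93.9% moved the same way (95% interval 87.3 to 97.7), which argues against probes that bind other transcripts in those genes. Another 168 genes beside BCAT1 had no such probe and stay open. Both intervals treat genes or probes as independent. Genes can vary together and some probes share a gene, so both intervals may be too narrow. Without a second hairpin or a rescue, the changes common to the lines cannot be assigned to BCAT1 alone.

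HIF1 targets were called as falling in all 3 lines with the preset correlation, and in MOLM13 alone with an estimated one (adjusted p = 0.458 in HL-60, 0.138 in SKM1 and 0.0421 in MOLM13); the list shares members with the glycolysis and MYC lists. Without those (n = 22 members left), camera still gave a fall in 2 of the lines, SKM1 (median -0.24, p = 8.04e-07) and MOLM13 (median -0.52, p = 4.46e-08), but not in HL-60 (median -0.13, p = 0.0540). With an estimated correlation the p-values were 0.0654, 0.0441 and 0.444 in SKM1, MOLM13 and HL-60. In HL-60 the full list had a median of -0.15, close to that without the shared members. The members left out there included LDHA (-1.11), ALDOC (-0.99) and HK2 (-0.79), which fell, and SLC2A3 (0.93), which rose. The lost call thus came with fewer members and without these changes, and the part of each in it stays open. A change in HIF1 activity through alpha-ketoglutarate, which its hydroxylases need, is a candidate explanation that these arrays did not test.

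Other splits of the arrays were counted for each result fitted across genes. Within a line there are 10 splits, too few for a share under 0.05: the real split gave 2881 changed genes in HL-60 and the highest other split 23, in SKM1 1704 and 0, and in MOLM13 3208 and 69, the real split being 1 of 10 in each. In MOLM13, where the numbers pair the arrays, the 3 other splits that part all 3 pairs gave at most 0 and the 6 that part 1 pair at most 69. Over the lines, 100 labellings were compared, the real one included. In the mean of the lines 1 of 100 gave as many genes (4263, against at most 1928 elsewhere), which argues against chance. For the differences between lines it was also 1 of 100 (2741 against 676). Labels were shuffled within lines, so this count asks whether the hairpins differ in any line, not whether the lines differ. In the genes shared by the lines it was 1 of 100 (443 against 0), but a labelling that calls few genes in any 1 line can share few, so this says nothing of sharing beyond the calls of each line. For the lists called in the mean, 3 of 100 gave as many as the real 17, with up to 20 elsewhere. This count is the least secure of those compared here. Other labellings with 0 changed genes also called lists, for example 10, 13 and 16 of the 32. They mix the hairpins and can keep part of the real difference, so they give no clean rate of false list calls. List calls made with the preset correlation alone are therefore weakly secured.

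The following differences between lines were found by a test of the difference itself. The F test called 2741 genes, and the pairwise tests 977 for SKM1 minus HL-60, 2226 for MOLM13 minus HL-60 and 1546 for MOLM13 minus SKM1. Of lists called in opposite directions, mitosis and G2/M differed by a median of -0.90 between MOLM13 and HL-60 (adjusted p = 7.03e-31, and adjusted p = 0.0167 with an estimated correlation), immediate early genes by -0.42 (adjusted p = 1.07e-06, and adjusted p = 0.150 with an estimated correlation), and heat shock and proteasome genes by -0.22 (adjusted p = 0.000330, and adjusted p = 0.201 with an estimated correlation). Between MOLM13 and SKM1 heat shock and proteasome genes differed by -0.23 (adjusted p = 5.49e-05, and adjusted p = 0.123 with an estimated correlation) and granule proteins by 0.84 (adjusted p = 1.07e-14, and adjusted p = 5.10e-05 with an estimated correlation).

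By the F test PRG2 had adjusted p = 6.48e-13, SCG2 2.78e-12, CCND1 2.84e-12, ADAMDEC1 1.97e-10, MPO 4.75e-10, ALOX5AP 6.54e-10, CSF1R 7.52e-10, PLAUR 3.91e-09, FCMR 5.06e-09 and STMN3 5.90e-09 (limma). Outside the genes of the comparisons, 10563 probes with no single gene name were bright enough to test, and 543 of them changed in the mean of the lines, with 392 in HL-60, 155 in SKM1 and 408 in MOLM13.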

How the results depend on the processing

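Among the tests in this part, the normexp background correction was chosen after the data were seen. BCAT1 kept its fall in each line under 17 alternatives, between -3.55 and -3.21 in HL-60 (largest adjusted p = 4.70e-10), -3.50 and -3.11 in SKM1 (2.39e-15) and -2.95 and -2.65 in MOLM13 (8.52e-08). Most counts stayed within 1.5 times their size. The exceptions were SKM1, with 3098 changed genes under array weights and 3000 with its own arrays alone, the counts at a minimum of 1.5-fold (663 in HL-60, 381 in SKM1, 779 in MOLM13 and 281 in the mean), and the lists called with an estimated correlation (4, 1, 9 and 3). With the mean of a gene's probes OGDH in HL-60 became -0.0128, RPL13 in SKM1 -0.0881 and in the mean -0.0366, and CAV1 in the mean -0.0048. Each of these is small, and of the 4 the RPL13 rise in the mean alone had been called. That setting also ended 34 calls of genes eligible for naming.

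Leaving out 1 array gave log2 fold changes of BCAT1 from -3.44 to -3.29 in HL-60, -3.30 to -3.23 in SKM1 and -2.85 to -2.73 in MOLM13. Changed genes numbered 2453 to 2670 in HL-60, 1186 to 1290 in SKM1, 2424 to 3414 in MOLM13 and 3861 to 4407 in the mean, 2177 to 3217 genes differed between lines, and 340 to 481 were shared by the lines. Called lists numbered 11 to 12, 9 to 12, 20 to 21 and 17 to 19. Each of these fits gave fewer genes in HL-60 and SKM1 than all arrays did. Genes eligible for naming made up 483 calls over the contrasts, and not all of them are named in the text. Of these calls 57 ended in at least 1 of these fits and none reversed. None of the 80 largest rises and falls ended (pairs of gene and contrast, BCAT1 in each contrast). Their choice as the largest called changes made this likely. Of 61 list calls 10 ended. Elsewhere list calls ended under the stricter filter (8) and with the mean of probes (1). Calls of eligible genes ended under array weights (9), robust variances (5), no filter (3), the normexp correction (11), the offset (1), single-line fits (16) and quantile normalization (1).

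With replicate numbers as a block, 3225, 1966 and 3502 genes changed in HL-60, SKM1 and MOLM13, 4606 in the mean, and 3114 differed between lines. With the block no called list or gene eligible for naming lost its call, and 16 eligible genes gained one. The called lists rose from 12 to 14 in HL-60 and from 11 to 14 in SKM1. Same-numbered arrays of HL-60 had r of 0.163, 0.0117 and 0.0959 and those of SKM1 -0.0975, -0.142 and 0.0403, so there the numbers do not pair arrays, and not every array correlated best with its own number. Quantile normalization and median centring moved the median of all genes by less than 0.01, and the share of rises among SKM1 calls from 41.8% to 45.8% under the former. Signal over the dim range limits what dim genes can show: 4758 were not tested.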

Other observations

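The test of gene families in this part was chosen only after the results had been seen; those of REST targets and of REST itself followed from seeing other genes rise, but were set before the tested values were seen.

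Beyond the lists, 244 families of genes with a common symbol stem and at least 8 tested members were compared with other genes by camera. Of 13 small nucleolar RNA host genes (SNHG), 9 fell in HL-60 and 8 in the mean of the lines (camera adjusted p = 1.59e-05 and 0.0420). Of 9 SIGLEC genes, sialic-acid-binding receptors of white blood cells, 6 rose in the mean (0.0332), and of 18 autophagy genes named ATG 8 rose (0.0420). In MOLM13, 8 of 11 MCM genes (5.83e-08), 11 of 29 kinesins (KIF, 0.00316) and 11 of 22 nucleoporins (NUP, 0.00256) fell. None of these families held with an estimated correlation, where every adjusted p lay above 0.2, with 0.381 and 0.622 for SNHG, 0.255 for MCM, 0.270 for KIF and 0.497 for NUP.

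Among the genes that rose, 3 that are best known from neurons were picked by eye and not from a list: SCG2 (log2 fold change 2.55 in HL-60, 1.05 in MOLM13 and -0.03 in SKM1), STMN3 (1.63 in the mean of the lines) and SYP (0.86, with shNT values at or below about the median of all probe values, so that its size is uncertain). Many neuronal genes are repressed outside neurons by the factor REST, and loss of that repression was set as a hypothesis and tested on 33 other REST targets, with the genes seen before left out. In the mean the list rose by camera (p = 0.00906, p = 0.0425 with an estimated correlation), with 9 members rising, among them RAB3C (0.67) and TMEM198 (0.48), and RUNDC3B (-0.40) falling; its median was only 0.03. By line camera gave p = 0.0139 in HL-60, 0.00905 in SKM1 and 0.369 in MOLM13, and 0.0538, 0.0425 and 0.450 with an estimated correlation (n = 33 members), so HL-60 was lost. The genes picked by eye followed the list by line only in part. In MOLM13, where the list was not past the test, STMN3 rose most (2.20) and SCG2 also rose. In SKM1, where the list rose, SCG2 did not and STMN3 rose least (0.72), though SYP rose most there (1.23). Weaker repression by REST may contribute to some of these rises. A lower REST transcript is argued against as the route, since REST had a log2 fold change of 0.0669 in the mean (SE 0.04, adjusted p = 0.257). Weaker repression by REST remains a hypothesis, found and tested on the same arrays.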
